A study of Homo sapiens and Mus musculus with 12 samples.

How the data were processed

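The data are 12 Agilent 2-colour arrays of 60-base oligonucleotide probes on 3 slides: 8 human arrays (4 with a 12-day and 4 with a 4-day undifferentiated reference) on slides 1 and 2, each slide holding 2 arrays of each group, and 4 mouse C2C12 arrays on slide 3. Per the labels, Cy3 carried undifferentiated and Cy5 differentiated cells on all 12 arrays. Dyes were not swapped, so a gene-specific dye bias cannot be told apart from the stage of the cells. The number of arrays and of cultures limits the precision.

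The deposited scanner files hold, per the file headers, the intensity of each spot and of its local background in both channels, from Agilent Feature Extraction 10.1.1.1. They also hold processed intensity values, background-subtracted and dye-normalized by that software, and a log10 ratio of Cy5 over Cy3 made from them, per the file headers. The authors' deposited value table holds a log2 ratio of Cy5 over Cy3 per probe. Its scale and direction were found by setting each column against its array, and its column medians lay between -0.00105 and 0.0335. Its background handling and centring method are not given in the sources used here. Per the submitters' processing notes limma 3.4.5 was used, with no step named. The deposited log2 ratios correlated with those computed here at r = 0.996 to 0.999 with a slope of 1.03 to 1.06.

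Mean spot intensity was corrected with the normexp model (offset 50) against the median local background, and log2 ratios were normalized within each array by loess (span 0.3, control spots at weight 0) in limma 3.58.1 (R 4.3.3, data.table version 1.17.8). Control spots were then left out, as were 84 to 209 spots per array that the scanner software marked as non-uniform or as outliers. These marked spots were also kept out of the fit of the normexp model. On several arrays a few of them, with a background far above their own signal, raised the fitted background spread to as much as 6877, against 0.532 to 2.38 without them. This choice was made after the data were seen, and the fit on all spots is an added alternative. Single-channel levels, used for bounds and for differences within a channel, are after loess and Aquantile scaling between arrays and are open to dye bias. Where a gene was not well above background in a channel on any array, its fold is a lower bound against the dimmest probe well above background on each array.

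Spots of a probe were averaged. Probes were kept if well above background in either channel on at least 50% of the species' arrays, which left 37236 of 41000 human and 34693 of 41174 mouse probes. A gene was represented by its brightest probe. Another probe of the gene passed in the opposite direction for 12 of 1434 human and 29 of 2003 mouse genes that passed and had further probes. Human probes were named through accessions of the supplied RefSeq gene names (24794 probes) and otherwise by the file's symbol, and 29976 had a symbol. Mouse probes keep the file's symbol (34709 probes), so some names are old. Mouse genes were matched to human ones by symbol, 1657 of the 13268 matched symbols through an older name. Coordinates are the files' own, in hg18 and mm7. No annotation of these builds was used here, so exons and untranslated regions are not given. Y-linked genes and XIST were left out.

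In human cells, arrays of 1 group on 1 slide were averaged, and limma's lmFit and eBayes were fitted to the 4 slide means with a coefficient per group. The mean of both coefficients, each alone and their difference were tested. In mouse cells the 4 arrays were fitted as replicates. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all kept probes. These choices, the groups, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. P-values measure the spread between these arrays, which is partly technical. The 23 gene lists cover the sarcomere, excitation-contraction coupling, the neuromuscular junction, myogenic regulators, adhesion and fusion, energy metabolism, the dystrophin complex, mitosis, DNA replication, cell cycle inhibitors, matrix and fibroblast genes, proteolysis, interferon, cholesterol, serum response, unfolded protein, insulin-like growth factor and cytokine genes, reference genes, and smooth muscle, adipocyte, endothelial and leukocyte markers. They were tested with camera at a preset correlation of 0.01, adjusted over the 23 lists. With an estimated correlation 0 of the 12 human, 10 reference-age and 10 mouse calls held. No called list changed the sign of its median under another background correction or scaling. Median centring moved the median of all genes from 0 to 0.11 in human cells, and the changes given are relative to that centre.

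Named genes were chosen by a fixed rule. For each species these were the 10 largest rises and 10 largest falls among genes that passed, changed the same way on every array and were well above background on every array. Added to them were up to 4 members of each list with the largest absolute ratio, any myogenic regulator, and the 5 largest changes in each class of genes shared between species. Some genes that met the rule are not reported here. Alternatives were no background correction, Agilent's processed signals, median centring, Aquantile scaling, the deposited table, other filters on dim probes, means over a gene's probes, other units of replication, the slide as a block, other list tests and leaving out arrays. The fits were tested on simulated data with known changes in randomly drawn genes. At a log2 change of 1, 2 and 3 the human fit recovered 55.2%, 79.1% and 84.8% of the changed genes among 18504, with 7 unchanged genes called. The mouse fit recovered 35.8%, 71.6% and 80.3% among 19451, with 5 unchanged genes called. A shifted list was found in both and no other list was. The simulated noise was independent between genes and, in mouse, between the 4 arrays, whereas the real mouse arrays formed pairs. The few false calls therefore do not measure the error of the mouse fit with paired arrays, nor that of camera with correlated genes. Nor do the human recovery and false calls measure the human fit with slide means that share a biological replicate. The real 4-day slide means shared 1 biological replicate of undifferentiated cells. With all 4-day arrays as 1 value no real gene passed.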

Results

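Gene expression was compared between undifferentiated and differentiated skeletal muscle cells of human and mouse on 12 Agilent 2-colour oligonucleotide arrays. Each array carried Cy3-labelled RNA of undifferentiated cells and Cy5-labelled RNA of differentiated cells, so every log2 ratio below is differentiated over undifferentiated. The human cells were primary skeletal muscle progenitors, differentiated for 8 days. On 4 arrays their undifferentiated counterpart had been collected 12 days after thawing (the 12-day reference), and on 4 arrays 4 days after thawing (the 4-day reference). The mouse cells were C2C12, an established myoblast line that forms multinucleate myotubes when serum is lowered. They were grown in 15% fetal bovine serum and differentiated for 5 days in 2% horse serum, on 4 arrays. Per the labels' protocols there were 2 biological replicates of the 12-day reference, 1 of the 4-day reference, 3 of the differentiated human cells and 2 of each C2C12 stage. Nothing in the labels says which arrays share an RNA.

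Signal was well above background for 63.6% to 88.5% of probes in Cy3 and for 79.4% to 91.6% in Cy5, and no spot was saturated. The median spot brightness ranged from 122 to 233 in Cy3 and from 208 to 487 in Cy5. Human arrays of 1 group on 1 slide differed about as much as spots of the same probe within an array (0.794 to 1.02 times that spread, r = 0.989 to 0.994 across probes). They were averaged to 1 value, which left 4 human values: the 12-day and the 4-day reference on each of 2 slides. The 12-day arrays of slide 1 stood apart, with r = 0.205 to 0.245 to every other human array. The 12-day arrays of slide 2 correlated with the 4-day arrays at r = 0.824 to 0.835, and the 4-day arrays of different slides at r = 0.979 to 0.987. Among the mouse arrays, replicates 1 and 3 and replicates 2 and 4 formed pairs with r = 0.991, at 1.11 to 1.12 times the spot spread, against r = 0.494 to 0.496 across the pairs. These correlations are across probes, which are not independent replicates.

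**Figure D1:**
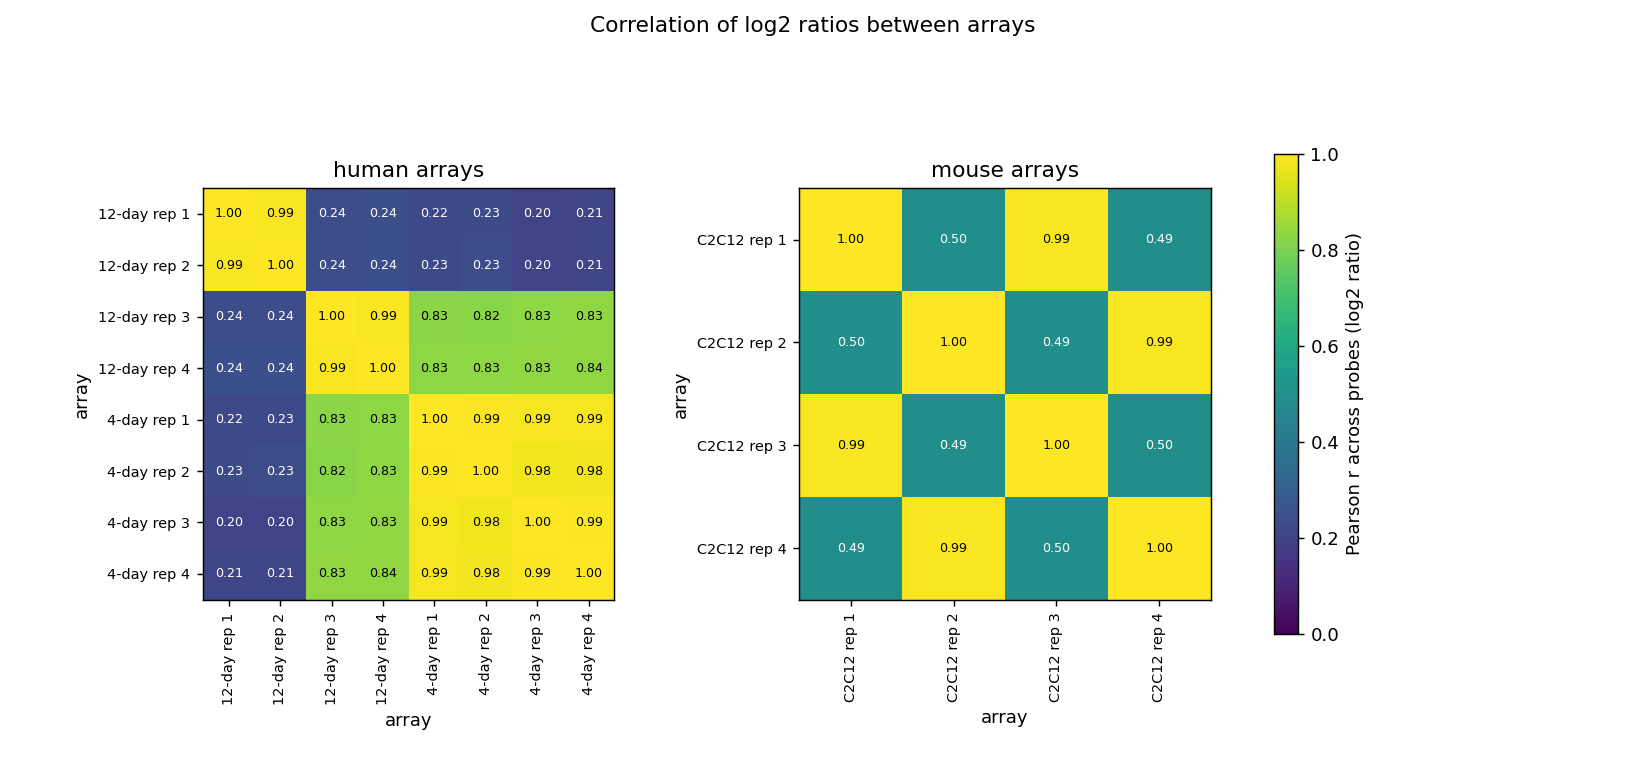
Pearson correlation, across probes, of the log2 ratio (differentiated over undifferentiated) between human arrays (left) and between mouse arrays (right), with both axes listing the arrays and the colour giving r. The 12-day replicates 1 and 2, on slide 1, correlate with the other human arrays at r = 0.205 to 0.245, and the mouse arrays fall into pairs.

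In human cells 19 of 45 sarcomere genes, 15 of 25 matrix genes and 13 of 21 cholesterol genes rose on differentiation, and 29 of 35 DNA replication genes and 11 of 32 mitosis genes fell. MYH3, the embryonic myosin heavy chain, rose 43.2-fold (log2 ratio 5.43 ± 0.715 SE, n = 4 slide means, limma adjusted p = 0.0314). IGFBP2, which binds insulin-like growth factors, rose 59.6-fold (log2 ratio 5.90 ± 0.239, adjusted p = 0.00909), and THBS4, a matrix glycoprotein of the thrombospondin family, rose 41.7-fold (log2 ratio 5.38 ± 0.0536, adjusted p = 0.00511). IL13RA2, a decoy receptor for interleukin 13, fell by 5.65 on the log2 scale (SE 0.782, adjusted p = 0.0335). PRG4, which encodes the lubricating proteoglycan of joints and tendon sheaths, fell by 4.39 (SE 0.147, adjusted p = 0.00802). Each of these genes changed the same way on all 4 slide means. The 4-day slide means share 1 biological replicate of undifferentiated cells, so the 4 slide means are not independent replicates.

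Across all 18504 genes tested with limma, 3334 passed an adjusted p of 0.05, of which 1895 were higher and 1439 lower in differentiated cells. Of these, 614 were at least 2-fold higher and 351 at least 2-fold lower. With median centring in place of loess the split was 5008 higher and 2231 lower, or 69.2% higher against 56.8%. Without a test, 374 genes were at least 2-fold higher and 78 at least 2-fold lower on all 4 slide means. Without the 12-day arrays of slide 1 these counts were 721 and 576. With those arrays left out, 12378 genes passed, 6243 higher and 6135 lower, but the spread then came from the 4-day arrays alone, whose reference was 1 biological replicate. With all 4-day arrays as 1 value no gene passed (2964 at an unadjusted p under 0.05), and none passed with the background model fitted on all spots (3575 at an unadjusted p under 0.05). With slide as a fixed term beside the groups, the 4 slide means gave 0 genes in limma (6143 at an unadjusted p under 0.05). Fitted within slide 1 alone 14759 genes passed and within slide 2 alone 14540, where the spread is that of duplicate arrays, and 88.2% and 87.3% of genes kept the sign of the pooled fit.

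The other large rises were those of SPRR2G (log2 ratio 5.82), SMOC2 (5.80), COL10A1 (5.31), EPYC (5.02), NOX4 (4.99), ITGA11 (4.95) and RARRES2 (4.77), with limma adjusted p from 0.00511 to 0.0299. SMOC2 encodes a secreted calcium-binding matrix protein, COL10A1 the collagen X chain, EPYC a small leucine-rich proteoglycan, NOX4 an NADPH oxidase and ITGA11 a collagen-binding integrin chain. The other large falls were CXCL2 (log2 ratio -4.17), CDCA2 (-3.79), HAS2 (-3.73), PCOLCE2 (-3.67), AREG (-3.66), NEFL (-3.60), LY6K (-3.27) and TNXB (-3.27), with adjusted p from 0.00624 to 0.0450. CXCL2 is a neutrophil-attracting chemokine, HAS2 makes hyaluronan, and AREG is a ligand of the epidermal growth factor receptor. On the 12-day arrays of slide 1 several of these changes were smaller. MYH3 had a log2 ratio of 2.54 there against 6.28 to 6.54 on the other slide means, SMOC2 3.14 against 6.50 to 7.0, IL13RA2 -2.82 against -6.92 to -6.40, and CDCA2 -0.87 against -5.41 to -3.50. THBS4 lay between 5.21 and 5.62 on all 4, and SPRR2G between 5.74 and 5.89. In build hg18, per the file headers, the THBS4 probe lies on chromosome 5 from 79414661 to 79414720, the IGFBP2 probe on chromosome 2 from 217237331 to 217237390, the IL13RA2 probe on chromosome X from 114144847 to 114144906, and the PRG4 probe on chromosome 1 from 184549440 to 184549499. The MYH3 probe spans chromosome 17 from 10472691 to 10473667.

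**Figure D2:**
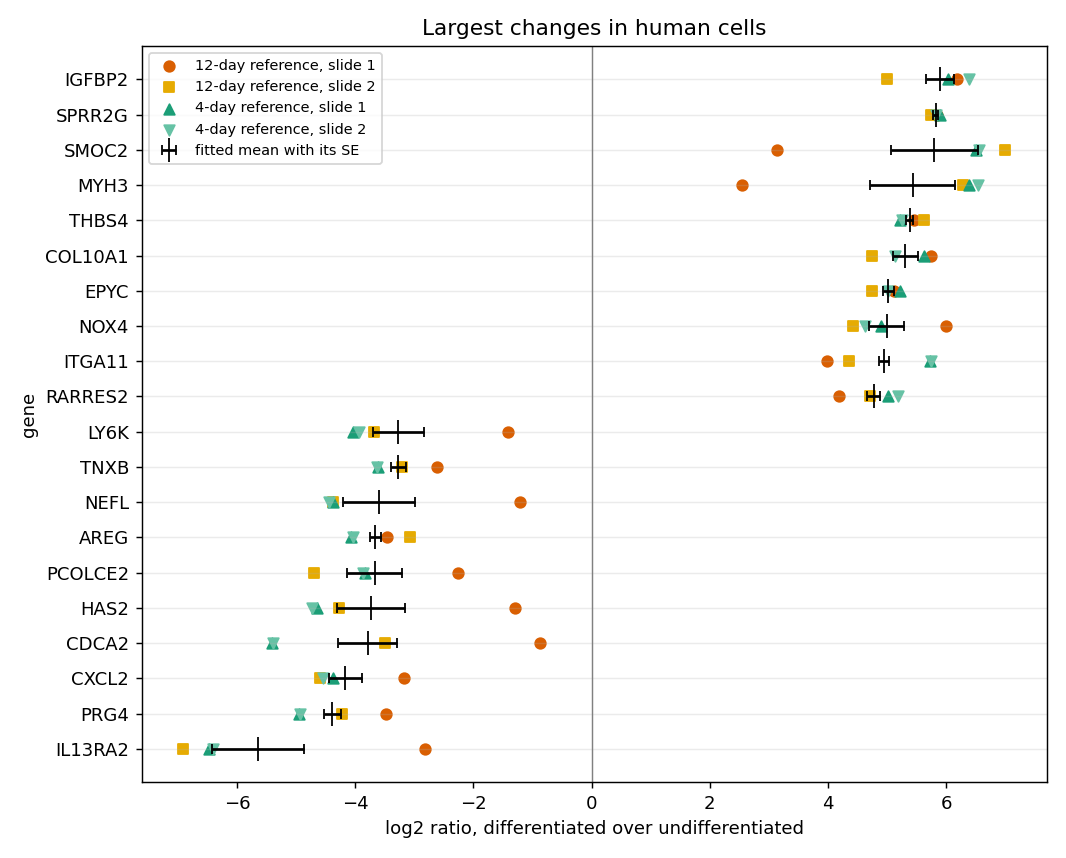
Log2 ratio (differentiated over undifferentiated, horizontal axis) of the human genes with the largest rises and falls, one gene per line, with a point per slide mean and a bar for the fitted mean and its SE. MYH3, SMOC2 and IL13RA2 lie nearer 0 on the 12-day arrays of slide 1, and SPRR2G and THBS4 do not.

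Of 45 measured human genes of the sarcomere and contractile apparatus, 19 rose, none fell and 26 did not pass (32 passed when adjusted over the list alone), with a median log2 ratio of 2.17. MYBPH rose 23.1-fold, MYL4 23.0-fold and ACTC1, the cardiac alpha-actin also made in developing skeletal muscle, 22.4-fold. The list rose as a set (camera, adjusted p = 2.69e-09; adjusted p = 0.594 with an estimated correlation). Its median was 0.36 on the 12-day arrays of slide 1 and 2.97 to 3.32 on the other slide means. Of 19 genes of excitation-contraction coupling and calcium handling, 7 rose and 12 did not pass (12 passed when adjusted over the list alone). The median was 0.39, and the set rose (camera, adjusted p = 0.0015; adjusted p = 0.559 with an estimated correlation). CASQ2, a calcium-binding protein of the sarcoplasmic reticulum, rose 15.2-fold, HRC 5.39-fold and JPH2 4.96-fold. The list's median was 0.11 on the 12-day arrays of slide 1 and 0.45 to 0.53 elsewhere. Of 11 genes of the acetylcholine receptor and neuromuscular junction, 5 rose and 6 did not pass (6 passed when adjusted over the list alone), with a median of 0.72 (camera, adjusted p = 0.00149; adjusted p = 0.504 with an estimated correlation). CHRNA1, the receptor's alpha subunit, rose 4.39-fold and DOK7 3.73-fold, and the list's median was 0.26 on the 12-day arrays of slide 1 and 0.50 to 0.92 elsewhere.

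Of 21 genes of myoblast adhesion and fusion, 9 rose, 1 fell and 11 did not pass (12 passed when adjusted over the list alone). JAM2 rose 14.5-fold, VCAM1 5.16-fold and DYSF, the membrane repair protein dysferlin, 4.50-fold. The set rose with a median of 0.34 (camera, adjusted p = 0.00523; adjusted p = 0.504 with an estimated correlation), and its median was 0.64 on the 12-day arrays of slide 1, 0.05 on those of slide 2 and 0.55 to 0.63 on the 4-day arrays. In the dystrophin complex and costamere 6 of 18 genes rose, 3 fell and 9 did not pass (13 passed when adjusted over the list alone). DMD, which encodes dystrophin, rose 10.4-fold and DES, the muscle intermediate filament desmin, 8.16-fold, but the set did not pass (camera, adjusted p = 0.350). Its median was 0.04 on the 12-day arrays of slide 1 and 0.27 to 0.61 elsewhere. In muscle energy metabolism 2 of 24 genes rose, 2 fell and 20 did not pass (6 passed when adjusted over the list alone). CKM, the muscle creatine kinase, had a log2 ratio of 2.05 ± 1.29 (adjusted p = 0.338), being -3.17 on the 12-day arrays of slide 1 and 3.59 to 3.96 elsewhere. That list's test pointed down (camera, adjusted p = 0.750) with a median of -0.01, while its mean was 0.17. Its median was -0.19 on the 12-day arrays of slide 1 and changed sign under 2 scalings.

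Among 23 myogenic regulators 2 rose, 2 fell and 19 did not pass (9 passed when adjusted over the list alone), and the set did not pass (camera, adjusted p = 0.596, median 0.05). MYOG, the myogenin transcription factor, rose 1.36-fold (log2 ratio 0.44 ± 0.0449, adjusted p = 0.0228) and EYA1 2.41-fold, while MYF6 fell by 0.89 and SNAI2 by 0.81 on the log2 scale. MEF2C had a log2 ratio of 2.99 ± 0.563 (adjusted p = 0.0540). MYF5, which marks committed myoblasts, had -2.61 ± 1.05 (adjusted p = 0.184), and ID1, an inhibitor of myogenic factors, -2.68 ± 0.795 (adjusted p = 0.113). On the 12-day arrays of slide 1 MYF5 was at 1.39 and ID1 at 0.79, and the list's median was 0.32. Of 14 genes of muscle proteolysis and atrophy, 4 rose and 10 did not pass (6 passed when adjusted over the list alone). FBXO32, the muscle ubiquitin ligase atrogin-1, rose 6.25-fold and MSTN, myostatin, 3.21-fold, and the set rose with a median of 0.48 (camera, adjusted p = 0.0196; adjusted p = 0.504 with an estimated correlation). Its median was 0.50 on the 12-day arrays of slide 1 and 0.38 to 0.50 elsewhere.

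Of 35 human genes of DNA replication, 29 fell, none rose and 6 did not pass (32 passed when adjusted over the list alone), with a median log2 ratio of -1.32. CDT1, which licenses replication origins, fell by 3.09 and TYMS, thymidylate synthase, by 2.88 on the log2 scale. The set fell (camera, adjusted p = 7.68e-17; adjusted p = 0.504 with an estimated correlation). Its median was -0.11 on the 12-day arrays of slide 1, -0.65 on those of slide 2, and -2.21 and -2.28 on the 4-day arrays. Of 32 mitosis genes 11 fell and 21 did not pass (31 passed when adjusted over the list alone), and all 32 had a negative mean ratio, with a median of -2.26. The set fell (camera, adjusted p = 3.16e-10; adjusted p = 0.594 with an estimated correlation). BUB1, a spindle checkpoint kinase, fell by 2.88 but was at 0.22 on the 12-day arrays of slide 1, and UBE2C, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, had a log2 ratio of -3.78 ± 0.720 (adjusted p = 0.0548). The median of the mitosis list was 0.21 on the 12-day arrays of slide 1, -2.06 on those of slide 2, and -3.51 and -3.60 on the 4-day arrays. Of 18 cell cycle inhibitors and exit genes 3 rose, 3 fell and 12 did not pass (8 passed when adjusted over the list alone), and the set did not pass (camera, adjusted p = 0.512, median 0.32). CDKN2B, which encodes the inhibitor p15, rose 11.9-fold, and the list's median was -0.26 on the 12-day arrays of slide 1.

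Of 25 extracellular matrix and fibroblast genes 15 rose and 10 did not pass (16 passed when adjusted over the list alone), with a median log2 ratio of 1.29. THBS2 rose 14.8-fold, POSTN, periostin, 14.4-fold and SPARC 4.57-fold, and the set rose (camera, adjusted p = 2.99e-06; adjusted p = 0.504 with an estimated correlation). Its median was 1.23 on the 12-day arrays of slide 1 and 0.88 to 1.64 elsewhere. Of 21 genes of cholesterol synthesis and uptake 13 rose and 8 did not pass (17 passed when adjusted over the list alone), with a median of 1.49. The synthetic enzymes HMGCS1 and DHCR7 rose 6.27-fold and 5.84-fold. The set rose (camera, adjusted p = 2.21e-09; adjusted p = 0.594 with an estimated correlation), with a median of 0.63 on the 12-day arrays of slide 1 and 1.70 to 1.85 elsewhere. Of 15 genes of the unfolded protein and amino acid stress list 6 rose and 9 did not pass (7 passed when adjusted over the list alone). PSAT1, an enzyme of serine synthesis, rose 5.22-fold and ASNS, asparagine synthetase, 3.01-fold, and the set rose with a median of 0.58 (camera, adjusted p = 0.0015; adjusted p = 0.504 with an estimated correlation). Its median was 0.64 on the 12-day arrays of slide 1.

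Of 25 interferon response genes 7 fell, 1 rose and 17 did not pass (12 passed when adjusted over the list alone). OAS1 and OAS3, which make the activator of RNase L, fell by 1.79 and by 1.75 on the log2 scale, and the set fell with a median of -0.60 (camera, adjusted p = 6.18e-04; adjusted p = 0.594 with an estimated correlation). Its median was -0.19 on the 12-day arrays of slide 1 and -1.0 to -0.93 elsewhere. Among 16 inflammatory cytokines CXCL2 alone fell, none rose and 15 did not pass (1 passed when adjusted over the list alone). The median was -1.18, and the set fell (camera, adjusted p = 0.0249; adjusted p = 0.731 with an estimated correlation). On the 12-day arrays of slide 1 its median was 0.69, against -1.62 to -1.39 elsewhere. Of 14 genes of the insulin-like growth factor system 5 rose, 1 fell and 8 did not pass (12 passed when adjusted over the list alone). IGF1, the secreted growth factor, rose 11.5-fold, but the set did not pass (camera, adjusted p = 0.0606, median 1.27), and its median was -0.10 on the 12-day arrays of slide 1.

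Smooth muscle, adipocyte, endothelial and leukocyte markers did not pass as sets in human cells (camera). Smooth muscle and myofibroblast markers had a median of 0.78 (adjusted p = 0.0688), with 3 of 10 genes higher, among them ACTA2, smooth muscle actin (6.33-fold), and MYH11 (3.89-fold). Their median was 2.18 on the 12-day arrays of slide 1 and -0.03 to 0.33 elsewhere. Adipocyte markers had a median of -0.40 and a mean of 0.03 with a test pointing down (adjusted p = 0.417), and none of 11 passed. Their median was -1.13 on the 12-day arrays of slide 1 and -0.15 to 0.03 elsewhere. Endothelial markers had a median of 0.02 (adjusted p = 0.672), with a change of sign under 2 scalings, and CLDN5, a tight junction protein, rose 5.95-fold. Leukocyte markers had a median of 0.15 (adjusted p = 0.439), with a change of sign under 1 scaling, and ITGB2, the beta-2 integrin chain, rose 15.9-fold. Adjusted over each list alone, 3 smooth muscle, 0 adipocyte, 1 endothelial and 7 leukocyte markers passed. Of 20 serum and immediate early genes 3 rose, 3 fell and 14 did not pass (10 passed when adjusted over the list alone). Their test pointed down (camera, adjusted p = 0.983) with a median of 0.16 and a mean of 0.29. Of 14 reference genes 4 were higher and 3 lower (7 passed when adjusted over the list alone), with a median of -0.23 (camera, adjusted p = 0.668) that changed sign under median centring.

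**Figure D3:**
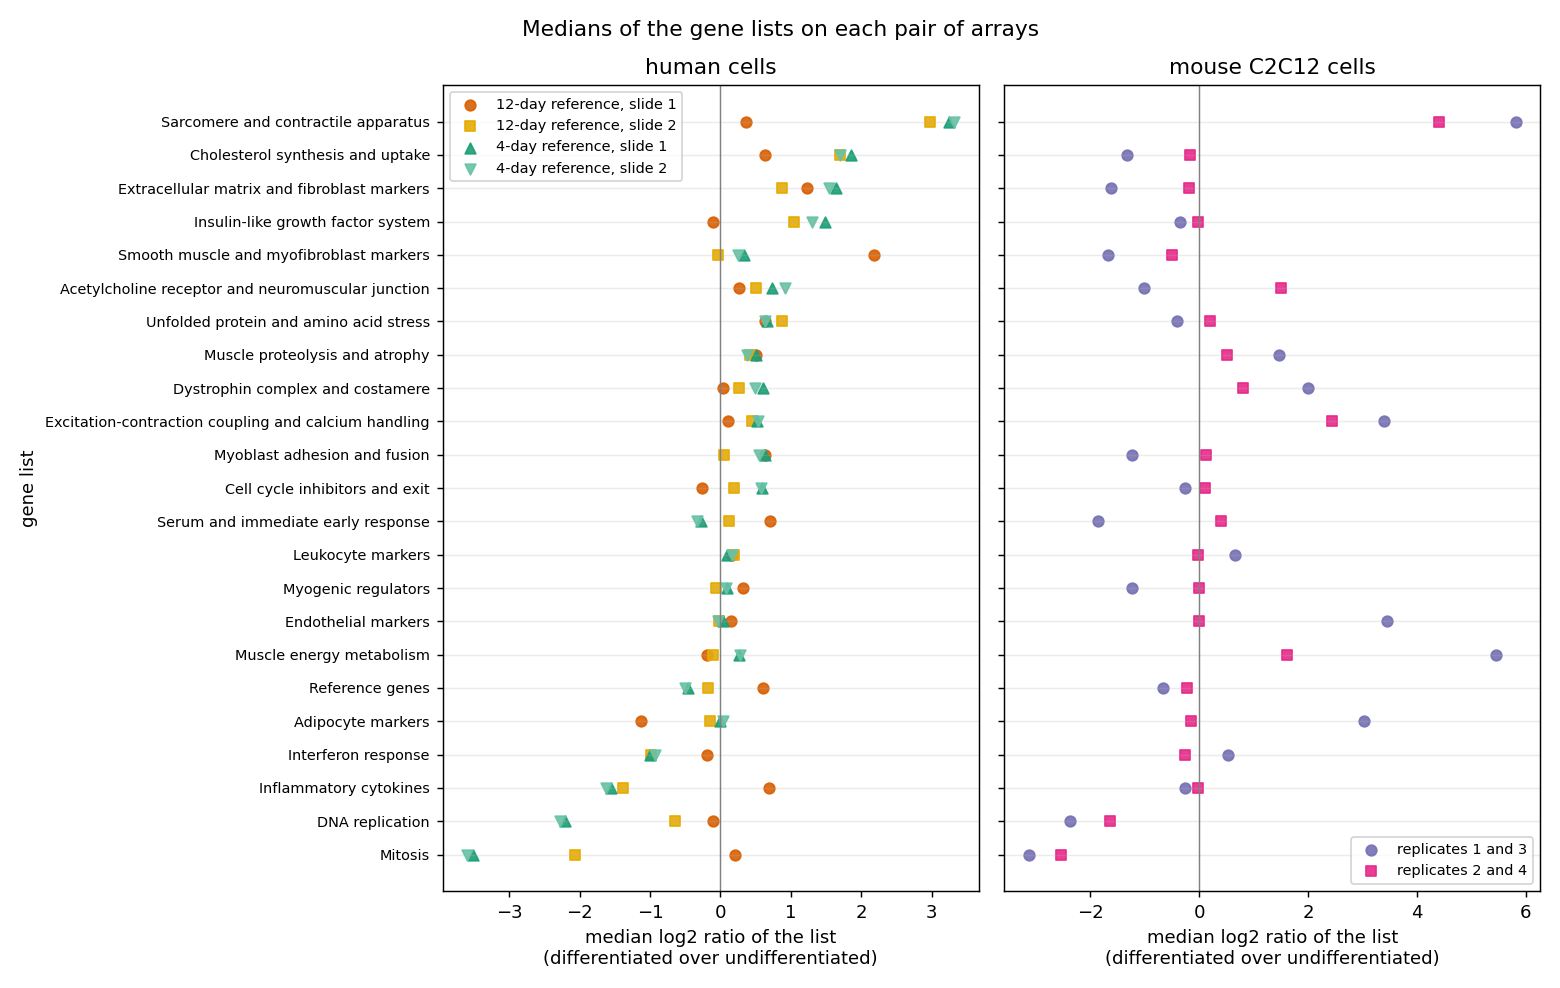
Median log2 ratio (differentiated over undifferentiated, horizontal axis) of each gene list (vertical axis) on each human slide mean (left) and each pair of mouse arrays (right). The mitosis list lies at 0.21 on the 12-day arrays of slide 1 and at -3.60 to -2.06 on the other human slide means, and the endothelial list at 3.45 on mouse replicates 1 and 3 and at 0.00 on replicates 2 and 4.

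Against the 12-day reference alone the human ratio rose for SPRR2G (log2 ratio 5.79, limma adjusted p = 0.0195), THBS4 (5.54, adjusted p = 0.0195) and IGFBP2 (5.59, adjusted p = 0.0383), each on both slides. Against the 4-day reference alone MYH3 rose too (log2 ratio 6.46, adjusted p = 0.0444), and its 12-day value was 4.41 (adjusted p = 0.152). In all, 287 of 18504 genes passed against the 12-day reference, 210 higher and 77 lower, and 2851 passed against the 4-day reference, 1532 higher and 1319 lower. With median centring the splits were 2149 to 411 and 2685 to 1076, or 83.9% higher against 73.2%, and 71.4% higher against 53.7%. The undifferentiated RNA of the 4-day arrays was 1 biological replicate, so its count holds no biological spread of that RNA. Both references share 1 spread estimate, to which the gap between the 12-day arrays of the 2 slides adds. MYH3 had an SE of 1.01 for each reference, with slide means of 2.54 and 6.28 (12-day) and 6.38 and 6.54 (4-day). Without the 12-day arrays of slide 1 the counts were 9257 and 12646, and with all 4-day arrays as 1 value both were 0 (1863 and 2033 at an unadjusted p under 0.05).

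The 12-day minus 4-day difference compares the ratios against the older and the younger undifferentiated cells, and with 1 biological replicate of the younger it does not separate their age from a difference between single cultures. The median difference was 2.75 for the mitosis list, which as a set fell less against the 12-day reference (camera, adjusted p = 1.99e-12; adjusted p = 0.581 with an estimated correlation) and 1.61 for DNA replication (camera, adjusted p = 7.95e-24; adjusted p = 0.581 with an estimated correlation). On slide 1 the median difference of the mitosis list was 3.91 and on slide 2 it was 1.59. The sarcomere list was lower in the 12-day ratio, with a median difference of -1.36 (camera, adjusted p = 4.34e-04; adjusted p = 0.654 with an estimated correlation). That difference was -2.31 on slide 1 and -0.23 on slide 2, and -0.17 without the 12-day arrays of slide 1 (adjusted p = 0.0373). For single genes the difference did not pass: BUB1 differed by 3.58 ± 1.01 (n = 4 slide means, limma adjusted p = 0.275), CDT1 by 2.29 ± 0.498 (adjusted p = 0.224) and DES by -2.20 ± 0.968 (adjusted p = 0.405). No gene passed (limma, smallest adjusted p = 0.185, 3271 genes at an unadjusted p under 0.05). Without the 12-day arrays of slide 1 the difference rests on a single 12-day slide mean. Its spread then comes from the 4-day arrays alone, whose reference was 1 biological replicate. Each slide held both references, and with slide as a fixed term the slide means gave 0 genes (limma, 2452 at an unadjusted p under 0.05). With the 8 arrays counted apart, slide as a random block gave 7850 and as a fixed term 7990.

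Of the 23 lists, 10 differed between the references. Higher in the 12-day ratio were also the serum and immediate early genes (median 0.55, adjusted p = 0.0314; adjusted p = 0.581 with an estimated correlation), the inflammatory cytokines (1.15, adjusted p = 0.0366; adjusted p = 0.744 with an estimated correlation) and the reference genes (0.51, adjusted p = 0.0137; adjusted p = 0.581 with an estimated correlation). Lower were also excitation-contraction coupling (-0.26, adjusted p = 0.0275; adjusted p = 0.581 with an estimated correlation), adhesion and fusion (-0.35, adjusted p = 0.0137; adjusted p = 0.581 with an estimated correlation), the dystrophin complex (-0.64, adjusted p = 0.0121; adjusted p = 0.581 with an estimated correlation) and cholesterol synthesis (-0.54, adjusted p = 0.0121; adjusted p = 0.706 with an estimated correlation). The other 13 lists did not pass (camera, adjusted p = 0.0860 to 0.993). Without the 12-day arrays of slide 1, 10 lists passed, of which 6 were among the first 10. Excitation-contraction coupling, cholesterol synthesis, serum response and cytokines then had adjusted p = 0.124, 0.717, 0.0518 and 0.377, with median differences of -0.13, -0.13, 0.17 and -0.19. The dystrophin complex was then at -0.43, adhesion and fusion at -0.38 and the reference genes at 0.26. Lists that passed only then were the matrix genes (median difference -0.5), the insulin-like growth factor system (-0.61), proteolysis and atrophy (-0.36) and the adipocyte markers (-0.18). That fit keeps a single 12-day slide mean.

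In C2C12 cells 34 of 45 sarcomere genes rose on differentiation and all 31 mitosis genes measured fell, in limma over 4 arrays. With each pair of arrays averaged to 1 value, 0 genes passed in limma (2391 at an unadjusted p under 0.05). Myot, which encodes the Z-disc protein myotilin, rose 271-fold (log2 ratio 8.08 ± 0.525 SE over 4 arrays, limma adjusted p = 0.00294). Myl1, a fast myosin light chain, rose 135-fold (log2 ratio 7.08 ± 0.446, adjusted p = 0.00282) and Myh2, a fast myosin heavy chain, 119-fold (log2 ratio 6.89 ± 0.420, adjusted p = 0.00264). Cenpe, a kinetochore motor, fell by 4.23 (SE 0.617, adjusted p = 0.0173) and Mki67, the proliferation marker Ki-67, by 4.03 (SE 0.528, adjusted p = 0.0133) on the log2 scale. Each changed the same way on 4 of 4 arrays. The limma p-values of mouse genes are too small, because the 4 arrays stand for 2 biological replicates of each stage.

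Of 19451 mouse genes tested with limma 4099 passed, 1721 higher and 2378 lower, of which 732 were at least 2-fold higher and 1183 at least 2-fold lower. With median centring the split was 2204 higher and 938 lower, or 70.1% higher against 42.0%, and the median of all genes moved from 0.07 to 0.13. Leaving out any 1 array gave 1238 to 1634 genes, and fitting the background model on all spots gave 1278. Without a test, 590 genes were at least 2-fold higher and 847 at least 2-fold lower in both pairs, and 196 were at least 2-fold higher in one pair and at least 2-fold lower in the other.

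The other large mouse rises were Smpx (log2 ratio 8.01), Pde4dip (7.55), Txlnb (7.06), Myl3 (6.86), Cox8b (6.66), Cacna1s (6.58) and Itm2a (6.43), with limma adjusted p from 0.00141 to 0.0131 over 4 arrays. Cox8b is a muscle subunit of cytochrome c oxidase and Cacna1s the voltage sensor of excitation-contraction coupling. The other large falls were Hgf (log2 ratio -4.16), Bub1 (-4.04), 5730507H05Rik (-3.93), Cks2 (-3.93), Slc1a6 (-3.91), Snai2 (-3.91) and Col8a2 (-3.88), with adjusted p from 0.00125 to 0.0391. Cxcl5, a chemokine, was not well above background in differentiated cells on any array and was at least 18.3-fold lower there (adjusted p = 0.00107). Hgf was well above background in differentiated cells on 3 arrays and Bub1 on 2. The rises were larger on replicates 1 and 3 than on replicates 2 and 4, at 9.17 against 6.99 for Myot, 9.27 against 5.84 for Pde4dip and 8.17 against 4.68 for Itm2a. So were most of these falls, at -5.52 against -2.95 for Cenpe, -5.13 against -2.93 for Mki67, -5.61 against -2.25 for Cks2 and -5.49 against -2.34 for Snai2, but not those of Slc1a6 (-3.63 against -4.18) and Cxcl5. The pairs did not differ in size alone: endothelial markers had a median of 3.45 on replicates 1 and 3 and of 0 on replicates 2 and 4. In build mm7, per the file headers, the Myot probe lies on chromosome 18 from 44733035 to 44733094, the Myl1 probe on chromosome 1 from 67164082 to 67164141, the Cenpe probe on chromosome 3 from 135067767 to 135067826 and the Mki67 probe on chromosome 7 from 132094802 to 132094861.

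**Figure D4:**
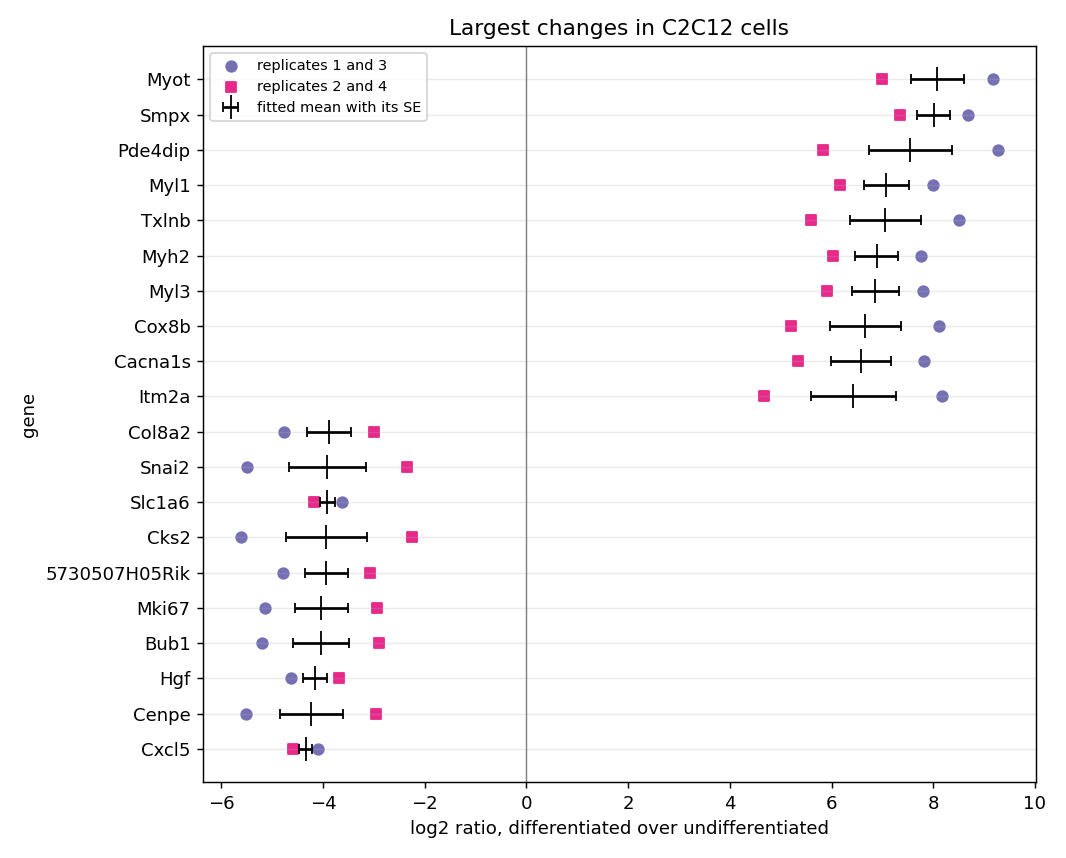
Log2 ratio (differentiated over undifferentiated, horizontal axis) of the mouse genes with the largest rises and falls, one gene per line, with a point per pair of arrays and a bar for the fitted mean over 4 arrays and its SE. Myot lies at 9.17 on replicates 1 and 3 and at 6.99 on replicates 2 and 4, and Cxcl5 is not well above background in differentiated cells.

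Of 45 sarcomere genes 34 rose, 1 fell and 10 did not pass in C2C12 cells (37 passed when adjusted over the list alone), with a median log2 ratio of 4.54, and 5.82 and 4.41 on replicates 1 and 3 and on replicates 2 and 4. The set rose (camera, adjusted p = 3.1e-15; adjusted p = 0.279 with an estimated correlation). Of 21 excitation-contraction coupling genes 14 rose and 7 did not pass (18 passed when adjusted over the list alone), with a median of 2.52 (3.4 and 2.43 in the pairs; camera, adjusted p = 2.76e-07; adjusted p = 0.394 with an estimated correlation). Hrc rose 36.4-fold (log2 ratios 5.93 and 4.44), Ryr1, the calcium release channel, 33.3-fold (6.15 and 3.96) and Trdn, triadin, 27.2-fold (5.70 and 3.83). Of 24 genes of muscle energy metabolism 11 rose, 1 fell and 12 did not pass (17 passed when adjusted over the list alone), with a median of 3.65 (5.45 and 1.62 in the pairs; camera, adjusted p = 9.39e-06; adjusted p = 0.575 with an estimated correlation). Cox6a2 rose 76.6-fold (log2 ratios 7.46 and 5.06 in the pairs), Ckm 49.2-fold (7.49 and 3.75) and Pgam2, the muscle phosphoglycerate mutase, 44.5-fold (6.82 and 4.13). In the dystrophin complex 11 of 18 genes rose and 7 did not pass (13 passed when adjusted over the list alone), with a median of 1.39 (1.99 and 0.81 in the pairs; camera, adjusted p = 6.13e-05; adjusted p = 0.279 with an estimated correlation). Itgb1bp2 rose 24.5-fold (log2 ratios 5.15 and 4.08) and Dmd 12.9-fold (4.58 and 2.81). Of 14 proteolysis and atrophy genes 3 rose and 11 did not pass (6 passed when adjusted over the list alone), with a median of 0.78 (1.47 and 0.51 in the pairs; camera, adjusted p = 0.0259; adjusted p = 0.367 with an estimated correlation). Trim63 and Trim54, muscle RING finger proteins, rose 52.9-fold and 33.2-fold (log2 ratios 6.56 and 4.89, and 5.90 and 4.20). The gene counts rest on limma p-values over 4 arrays, which are too small. The list p-values, which camera takes from the spread between genes, were with pairs averaged 9.49e-23, 1.84e-10, 9.42e-09, 4.56e-06 and 0.0103 in this order (camera, adjusted). On replicates 1 and 3 alone the proteolysis and atrophy list did not pass (camera, adjusted p = 0.0938, against 0.0257 on replicates 2 and 4 alone). The other lists of this paragraph passed on each pair alone.

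All 31 mitosis genes measured in C2C12 cells fell (31 passed when adjusted over the list alone), with a median log2 ratio of -2.81 (-3.13 and -2.54 in the pairs), and the set fell (camera, adjusted p = 2.18e-21; adjusted p = 0.367 with an estimated correlation). Of 34 DNA replication genes 31 fell and 3 did not pass (34 passed when adjusted over the list alone), with a median of -1.96 (-2.38 and -1.63 in the pairs; camera, adjusted p = 1.57e-18; adjusted p = 0.367 with an estimated correlation). Uhrf1 fell by 3.67 (-4.40 and -2.94 in the pairs), Mcm6, a subunit of the replicative helicase, by 3.58 (-4.61 and -2.55) and Prim1, a primase subunit, by 3.06 (-3.81 and -2.31) on the log2 scale. Of 25 matrix and fibroblast genes 4 fell, 2 rose and 19 did not pass (6 passed when adjusted over the list alone), with a median of -1.18 (-1.62 and -0.18 in the pairs; camera, adjusted p = 0.0151; adjusted p = 0.508 with an estimated correlation). Fbln1 fell by 2.44 on the log2 scale (-1.62 and -3.25 in the pairs) and Dcn, decorin, rose 13.3-fold (log2 ratios 5.46 and 2.01). Of 10 smooth muscle markers 2 fell, Cnn1 by 1.83 and Tgfb1i1 by 1.33 on the log2 scale (3 passed when adjusted over the list alone), with a median of -0.90 (-1.68 and -0.50 in the pairs; camera, adjusted p = 0.0218; adjusted p = 0.372 with an estimated correlation). Of 21 cholesterol genes 2 fell and 19 did not pass (2 passed when adjusted over the list alone), with a median of -0.65 (-1.33 and -0.17 in the pairs; camera, adjusted p = 0.00336; adjusted p = 0.575 with an estimated correlation). Sqle, squalene epoxidase, had a log2 ratio of -1.52 ± 0.636 (adjusted p = 0.166). The limma p-values behind the gene counts are too small. With pairs averaged the adjusted p of the lists was 6.8e-27, 9.49e-23, 0.00959, 0.0137 and 0.00217 in this order (camera). On replicates 2 and 4 alone the matrix (camera, adjusted p = 0.126) and cholesterol lists (adjusted p = 0.344) did not pass. On replicates 1 and 3 alone the smooth muscle markers did not (camera, adjusted p = 0.0998). The mitosis and DNA replication lists passed on each pair alone.

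Among 23 mouse myogenic regulators 3 rose, 7 fell and 13 did not pass (11 passed when adjusted over the list alone), and the set did not pass (camera, adjusted p = 0.161, median -0.69). Mef2c rose 26.6-fold, Mef2d 3.45-fold and Mef2a 3.08-fold, while Id2 fell by 2.79 (-3.82 and -1.76 in the pairs), Id3 by 2.78, Myf5 by 2.54 and Id1 by 1.86 (-2.67 and -1.05) on the log2 scale. Myod1 had a log2 ratio of -1.38 ± 0.441 (adjusted p = 0.103). Myog was at -2.07 on replicates 1 and 3 and at 3.20 on replicates 2 and 4, with a mean of 0.57 ± 1.26 (adjusted p = 0.754). In adhesion and fusion 3 of 21 genes rose, 2 fell and 16 did not pass (5 passed when adjusted over the list alone). Cav3, the muscle caveolin, rose 37.0-fold and Dysf 5.52-fold, and the set did not pass (camera, adjusted p = 0.161, median -0.43). At the neuromuscular junction Ache, acetylcholinesterase, rose 4.22-fold and Chrne, the adult receptor subunit, 3.75-fold, and the other 7 genes did not pass (2 passed when adjusted over the list alone). That list had a median of -0.05, a mean of 0.41 and a test pointing up (camera, adjusted p = 0.422), with medians of -1.02 and 1.51 in the pairs and a change of sign under 2 scalings. The limma p-values of these genes are too small, and with pairs averaged the 3 lists had adjusted p = 0.160, 0.161 and 0.332 (camera). On replicates 1 and 3 alone the 3 lists passed (camera, adjusted p = 0.0207, 0.000594 and 0.0453). On replicates 2 and 4 alone only the neuromuscular junction list did (camera, adjusted p = 0.000329), with a median of the opposite sign.

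Mouse endothelial markers had a median of 3.45 on replicates 1 and 3 and 0.00 on replicates 2 and 4 (camera, adjusted p = 0.0560, 0.0137 with pairs averaged and 0.690 with an estimated correlation, none of 10 genes passed), and adipocyte markers 3.03 and -0.16 (adjusted p = 0.495). Cdh5, an endothelial cadherin, was at 5.09 and 0.20 and Adipoq, the fat cell hormone adiponectin, at 5.71 and 0.05. Of 14 adipocyte markers Cd36 rose 28.1-fold (log2 ratios 5.98 and 3.65 in the pairs), 2 fell and 11 did not pass. Leukocyte markers had medians of 0.66 and -0.03 (adjusted p = 0.161, none of 9 passed). Cell cycle inhibitors (median -0.14, adjusted p = 0.273, Ccnd1 lower by a log2 ratio of -2.37), interferon response genes (0.01, adjusted p = 0.978) and serum response genes (-0.67, adjusted p = 0.0718) did not pass as sets. Nor did the unfolded protein list (-0.15, adjusted p = 0.939), the insulin-like growth factor system (-0.08, adjusted p = 0.221) and reference genes (-0.27, adjusted p = 0.161). The inflammatory cytokines had a median of 0.01, a mean of -0.35 and a test pointing down (adjusted p = 0.273), with Cxcl1 lower by a log2 ratio of -3.27. Medians of the cytokine, growth factor and unfolded protein lists changed sign under 1 scaling each. In this order, the number that passed when adjusted over the list alone was 0, 3, 0, 6, 3, 4, 1, 7, 6 and 3, from limma p-values that are too small. With pairs averaged the endothelial (camera, adjusted p = 0.0137) and serum response lists (adjusted p = 0.0425) passed, against adjusted p = 0.690 and adjusted p = 0.654 with an estimated correlation over 4 arrays, and the other 8 had adjusted p = 0.161 to 0.983. On replicates 1 and 3 alone the endothelial, adipocyte, leukocyte and serum response lists passed (camera, adjusted p = 0.000501, 0.0023, 0.0453 and 0.000174). On replicates 2 and 4 alone the interferon and unfolded protein lists did (camera, adjusted p = 0.0196 and 0.0493).

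The genes changed in both species were compared over 12035 genes matched by symbol. HSPB3, a small heat shock protein of muscle, rose in both (log2 ratio 4.57 in human, 4.79 in mouse), as did MYBPH (4.53 and 5.19), MYH2 (4.26 and 6.89) and MYH1 (3.99 and 5.85). On the human 12-day arrays of slide 1 these were at 1.48 (HSPB3), 1.24 (MYBPH), 1.33 (MYH2) and 1.24 (MYH1). SPAG5, CDT1, SHCBP1, BUB1 and TYMS fell in both, with log2 ratios of -3.06 and -3.06, -3.09 and -2.94, -2.89 and -3.46, -2.88 and -4.04, and -2.88 and -2.84. On the human 12-day arrays of slide 1 SPAG5 was at -0.27, CDT1 at -1.30, SHCBP1 at 0.05, BUB1 at 0.22 and TYMS at -2.05, and without those arrays BUB1 had a human log2 ratio of -3.54, SHCBP1 -3.51 and SPAG5 -3.67. In the mouse pairs Tyms was at -4.02 and -1.66, Bub1 at -5.19 and -2.90, Shcbp1 at -4.18 and -2.75, Cdt1 at -3.67 and -2.21 and Spag5 at -3.34 and -2.79. In all, 215 genes rose in both against 146 with independent lists (one-sided Fisher exact p = 8.37e-10), and 347 fell in both against 156 (one-sided Fisher exact p = 3.34e-55). The mouse p-values behind these calls are too small, and no gene was shared with the mouse pairs averaged. The Fisher tests count genes as independent, which genes regulated together are not.

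IGFBP2 rose in human cells and fell in C2C12 (log2 ratios 5.90 and -3.64), as did SULF2, a sulfatase of heparan sulfate (3.34 and -3.57), COL8A2 (2.91 and -3.88), COL12A1 (3.58 and -2.82) and ANXA3 (2.39 and -2.21). In the other direction were FGFBP1 (-2.40 and 2.51, with 0.07 on the human 12-day arrays of slide 1), CLU, clusterin (-2.13 and 3.23), HSD11B1 (-1.78 and 1.24), PACSIN3 (-1.19 and 3.26) and CTSC, cathepsin C (-1.15 and 4.53). In all, 145 genes were higher in human and lower in mouse against 206 with independent lists, and 61 were lower in human and higher in mouse against 111 (one-sided Fisher exact p = 1 for both). That test looks for an excess only, so these shortfalls were not tested. Across the matched genes, which are not independent replicates, the log2 ratios of the species correlated with Pearson r = 0.219 and Spearman rho = 0.119. The species were measured on different array designs, so the difference in size between them was not tested.

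**Figure D5:**
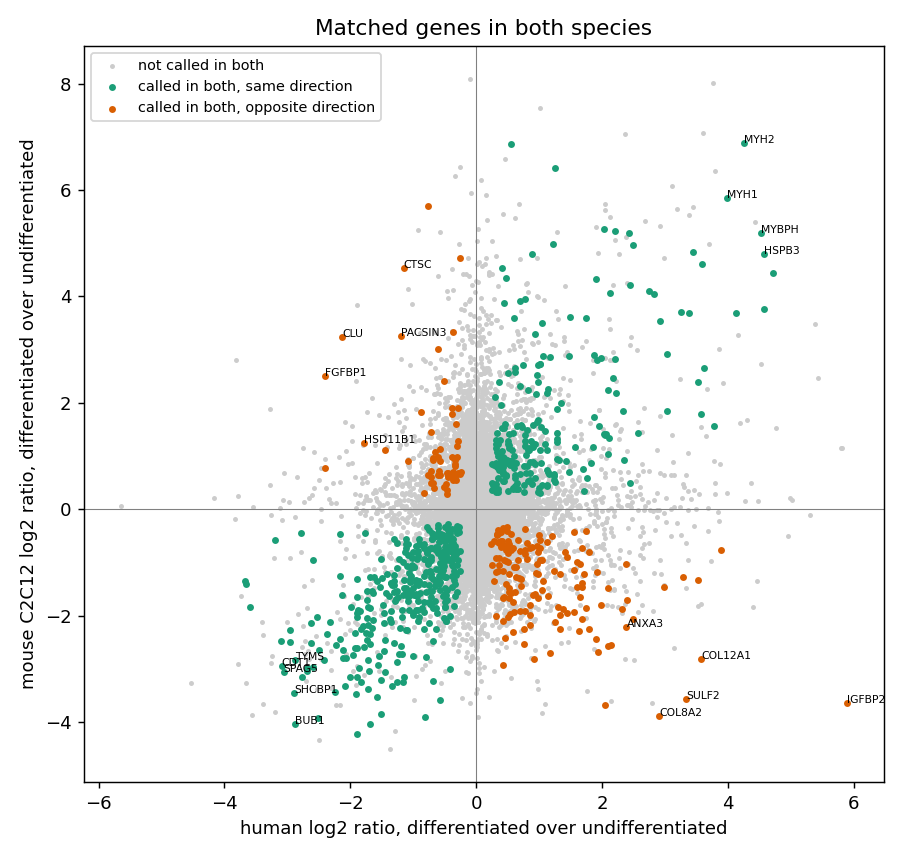
Log2 ratio (differentiated over undifferentiated) of the matched genes in human cells (horizontal axis) and in C2C12 cells (vertical axis), with 1 point per gene and colour for genes that passed in both species. MYH2 lies at 4.26 and 6.89, and IGFBP2 at 5.90 and -3.64.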

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

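The tests of the human arrays that stood apart, of the mouse pairs and of the age of the culture were chosen only after the results were seen, and so was the limit to splits that keep duplicate arrays together, while the count of other splits was planned before.

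The 12-day arrays of slide 1 stood apart from the other human arrays, mainly in the undifferentiated channel (Cy3 difference 0.447 to 0.538, Cy5 0.108 to 0.200). A difference between slides is argued against by the 4-day arrays, which correlated across the same slides at r = 0.979 or more. The 12-day arrays of slide 2 reached at most r = 0.245 with those of slide 1. That argues against an effect of 12 days in culture that is equal on both slides. Cultures of that age that changed to different degrees would give a low r too, so time in culture itself is not decided. Differentiated RNA mixed into the undifferentiated sample would pull ratios toward 0, but 156 genes at least 2-fold one way on the other 3 slide means were at least 2-fold the other way here (63 higher and 93 lower elsewhere). RNA of fat cells may have added to that channel as a hypothesis, since 63.6% of the adipocyte markers (7 of 11) were at least 2-fold higher there against 8.44% of all genes. CFD was at a log2 level of 15.56 against 11.62, SCD at 14.37 against 10.08 and CD36 at 13.45 against 8.88. The fat cell hormone ADIPOQ (8.83 against 7.16) and PLIN1 (7.68 against 6.33) were higher too, though at lower levels. DGAT2 was lower there (8.09 against 10.48). Of the 11 measured, CD36, SCD, CEBPB and DGAT2 are also expressed in muscle (CD36 and SCD among the 7) and 0 are in another list. AGPAT2, CEBPA and CEBPB differed by -0.45, 0.04 and -0.27, and the design names no sort or gate. Fat cell RNA leaves the sarcomere genes open, of which 34 of 45 (75.6%) were at least 2-fold higher there too (CKM 14.80 against 7.58). All 32 mitosis genes were at least 2-fold lower there, with a median difference of -4.04. Added fat cell RNA would not bring such a fall, so these values argue against it as the whole source. Higher sarcomere and lower mitosis genes are also the direction of differentiation on the other 3 slide means. Whether the cells of this reference were still undifferentiated was not tested.

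The mouse arrays of replicates 1 and 3 stood apart from those of replicates 2 and 4, in the differentiated channel. A difference in the undifferentiated channel is argued against, since Cy3 differed between the pairs 1.11 times as much as within them and Cy5 5.56 times as much. RNA of endothelial and of fat cells in the differentiated sample may have contributed, as a hypothesis: 90% of the endothelial (9 of 10) and 85.7% of the adipocyte markers (12 of 14) were at least 2-fold higher in Cy5 of replicates 1 and 3, against 13.7% of all genes. Cfd had a log2 level of 17.67 against 6.36, Fabp4 16.90 against 7.01, Flt1 13.32 against 7.49 and Vwf 13.02 against 8.38. Muscle genes differed as well (Ckm 18.47 against 11.78, Myh3 11.40 against 17.27, Myog 12.31 against 17.02). Of 24 genes of muscle energy metabolism 22 were at least 2-fold higher there (median difference 2.93). Of 21 adhesion and fusion genes 15 were at least 2-fold lower (median difference -1.37). Added RNA of endothelial and fat cells alone would not move muscle lists in opposite directions, so these values argue against those cells as the whole source. They do not decide on RNA of any other source, which was not tested. Eng, Cd36, Lpl, Scd1, Cebpb and Dgat2 are also expressed in muscle cultures, and no sort or gate is named. The design names no biological difference between the pairs, so none of its own was tested.

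The human mitosis list fell less against the 12-day than against the 4-day reference (camera, adjusted p = 1.99e-12; adjusted p = 0.581 with an estimated correlation). The 12-day arrays of slide 1 are argued against as the whole source, since the median difference of the mitosis list was 1.59 on slide 2 and 3.91 on slide 1. Of the 35 splits of the 8 arrays only 3 keep duplicate arrays of a group and slide together, too few for a share under 0.05: with the arrays taken as independent the real split gave 5803 genes and the highest other 0 (1 of 3 as large). The age of the undifferentiated culture, the biological difference the design names, cannot be told apart from a difference between single cultures, because the 4-day reference had 1 biological replicate.

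As sets, these lists had ratios that differed between the 12-day and the 4-day reference by a test of the difference (camera): mitosis by a median of 2.75, DNA replication by 1.61, inflammatory cytokines by 1.15, serum response by 0.55, reference genes by 0.51, sarcomere by -1.36, the dystrophin complex by -0.64, cholesterol synthesis by -0.54, adhesion and fusion by -0.35 and excitation-contraction coupling by -0.26. With an estimated correlation 0 did (adjusted p = 0.581 or more). Without the 12-day arrays of slide 1 the medians were 1.59, 1.57, -0.19, 0.17, 0.26, -0.17, -0.43, -0.13, -0.38 and -0.13 in this order, and the cytokine (adjusted p = 0.377), serum response (0.0518), cholesterol (0.717) and coupling (0.124) lists did not pass.

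Some genes went one way on every human array and the other way on every mouse array, and these differences were not tested. They were IGFBP2 (human log2 ratio 5.90, mouse -3.64), COL12A1 (3.58 and -2.82), IGF1 (3.53 and -1.32), SULF2 (3.34 and -3.57), COL8A2 (2.91 and -3.88), ANXA3 (2.39 and -2.21), CLU (-2.13 and 3.23), HSD11B1 (-1.78 and 1.24), PACSIN3 (-1.19 and 3.26) and CTSC (-1.15 and 4.53).

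Within groups of 4 arrays, 1 array lay far from the other 3 by Dixon's test in 4 of the 227 gene groups and 24 groups of array measures tested. Chance gives about 1 in 20 groups for independent arrays. The 12-day and mouse groups were pairs of near duplicates that stood apart, where 1 array can hardly lie far from the other 3. The test could therefore not find those pairs. TYMS was at -1.99 on a 12-day array against a group median of -2.11, and on 4-day arrays SNAI2 was at -0.86 against -0.99, MYH1 at 5.03 against 4.94 and HSD11B1 at -1.23 against -1.20.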

How the results depend on the processing

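Chosen only after the results were seen were the fit of the background model on all spots, leaving out the 12-day arrays of slide 1 or a mouse pair, taking the 4-day arrays as 1 value, slide means with slide as a fixed term, the list tests with mouse pairs averaged, and the shared genes with mouse pairs averaged. So were the list tests and the shared genes without any 1 array. Where no cause is given below, it was not tested.

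For the human mean ratio, 3334 genes passed in limma. Median centring gave 7239, 8 independent arrays 10847, slide as a random block 7498 and as a fixed term 12180, slide 1 alone 14759 and slide 2 alone 14540. For the 12-day reference (287) the same settings gave 2560, 7447, 5684, 9372, 14092 and 13272. For the 4-day reference (2851) all but median centring moved it beyond 1.5-fold, to 10396, 8894, 11771, 14263 and 13983. For the 12-day minus 4-day difference (0, with 3271 at an unadjusted p under 0.05) they gave 5803, 7850, 7990, 13218 and 11163. Arrays of 1 group on 1 slide differ about as much as spots within an array, so fits that count them apart have a smaller spread by construction. Leaving out the 12-day arrays of slide 1 keeps a single 12-day slide mean, and the spread is then that of the 4-day arrays alone.

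Leaving out the 12-day arrays of slide 1 gave 12378 (mean), 9257 (12-day), 12646 (4-day) and 7129 (difference). With all 4-day arrays averaged to 1 value limma gave 0, 0 and 0 for the first 3 (2964, 1863 and 2033 at an unadjusted p under 0.05). With normexp fitted on all spots it gave 0, 0 and 0 (3575, 1707 and 3593). In that fit a few marked spots raised the background spread, in Cy5 of 4-day replicate 3 to 6877 against 1.288 without them. Slide means with slide as a fixed term gave 0, 0 and 0 (6143, 3482 and 5819), and 0 for the difference (2452), from 1 fewer degree of freedom. Leaving out 1 array gave 3121 to 3458, 227 to 309 and 2664 to 2902 genes.

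The replicate numbers do not pair the human groups: deviations of arrays with the same number correlated at r = 0.0327, 0.126, 0.0997 and 0.0628, not all over 0.1. With the number as a replicate block the difference gave 4544 genes.

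For C2C12, 4099 genes passed. Averaging replicates 1 and 2 and replicates 3 and 4 gave 15036, replicates 1 and 4 and replicates 2 and 3 gave 15459, and replicates 1 and 3 and replicates 2 and 4 gave 0 (limma, 2391 at an unadjusted p under 0.05). The first and second set average across the pairs that stood apart, which removes that spread by construction. With normexp fitted on all spots 1278 passed, without replicates 1 and 3 12933, without replicates 2 and 4 14806, and without any 1 array 1238 to 1634. Myog, at 0.57, was at -2.07 without replicates 2 and 4 and between -0.32 and 1.46 without any 1 array.

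Of the genes changed the same way in both species (562), 206 were at least 2-fold in both, and 37 were shared with the 12-day reference alone. The count was 0 with mouse pairs averaged, 0 with normexp fitted on all spots and 0 with the 4-day arrays as 1 value, which left 0 genes in one species. It was 1536 without the 12-day arrays of slide 1, 1284 without mouse replicates 1 and 3, 1191 without replicates 2 and 4, and 244 to 591 without any 1 array.

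Of the gene lists, 12 (human), 10 (difference) and 10 (mouse) passed with camera, 0, 0 and 0 with an estimated correlation, and 11, 0 and 13 with fry. In human cells camera had 8 lists up and 4 down and fry 10 up and 1 down, of which 8 were called by both. In mouse, 12 passed with camera and pairs averaged (6 up, 6 down), 10 of them the same. Without replicates 1 and 3, 11 passed, and without replicates 2 and 4, 15 passed (camera). Each of these fits kept 8 of the 10.

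The other planned settings (no background correction, Agilent's processed signals, the deposited table, other filters on dim probes, means over probes) left the counts within 1.5-fold. Aquantile scaling moved no log ratio and so tests nothing. Turning arrays was not run because no array was turned. Over all settings, 1650 of 1900 values of 76 named human genes stayed the same, 221 were weaker, 29 stronger and 0 reversed, and 1146 of 1349 mouse values stayed the same, 178 were weaker, 22 stronger and 3 reversed. Settings that change only the spread, such as independent arrays or slide as a block, leave the mean ratio as it is. No sign could reverse there, so the count of 0 says little about direction.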

Other observations

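These values were looked up only after the results were seen. In the undifferentiated channel the 12-day arrays of slide 1 had MYH8, the perinatal myosin heavy chain, at a log2 level of 15.10 against 8.70 on the other human arrays, ACTA1, skeletal alpha-actin, at 15.18 against 9.94 and PPARG at 12.02 against 8.93. All 32 mitosis genes were at least 2-fold lower there, with a median difference of -4.04. These are levels within 1 channel and are open to dye bias.

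In the differentiated channel, mouse replicates 1 and 3 had the adult fast myosin Myh4 at a log2 level of 18.96 against 14.82 on replicates 2 and 4. Genes of muscle energy metabolism were at least 2-fold higher there for 22 of 24, with a median difference of 2.93. Adipoq was at 13.91 against 6.54 and Cdh5 at 11.68 against 6.46.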
